A study of Mus musculus with 10 samples.

How the data were processed

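RNA from sorted lineage-negative, Sca1-positive, cKit-positive marrow cells was amplified, labelled with biotin and read on whole-genome mouse expression arrays from Affymetrix, per the labels' protocols. Recipient mice had been transplanted 5 weeks before induction with donor marrow carrying the tamoxifen-inducible Cre, received 3 injections of 75 mg/kg tamoxifen, and were analysed 4 weeks after it, per the labels' protocols. The labels called samples of one group biological replicates but did not say that each came from its own animal, so p-values measure the spread between these samples. Samples were assigned to 4 groups from the genotype in their labels: β-heterozygous (n = 2), β-floxed (n = 2), α-null (n = 3) and double (n = 3).

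The values were the deposited log2 expression values, 1 per probe set and array, for 45101 probe sets and 10 arrays. The authors obtained them by RMA, with Partek also named, per the submitters' processing notes. Versions and settings, and whether all arrays were normalized together, are not given in the sources used here. The arrays' distributions were not identical, as the interquartile ranges of 2.25 to 2.97 showed. The number of arrays limits the precision. Scanner files were not used here.

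Probe sets were named from the platform's annotation: 34945 named 1 gene, 932 several, 9160 none, and 64 were controls. Only those naming 1 gene were used, and 34741 of them matched the RefSeq gene table of GRCm38.p6 by Entrez identifier, with 0 symbols changed. A gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes, 9010 of them with several probe sets. Genes were tested if that mean lay above the 30th percentile of all probe sets, 6.39 log2 units, which left 14751. That level is not a measured background, and no detection calls were used. In 37 reported pairs of gene and comparison, all arrays of a compared group lay under it, so the size of those changes depends on how low the arrays can read.

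Differential expression was tested with limma 3.58.1 in R 4.3.3, as lmFit with 1 mean per group over all 10 arrays (6 residual degrees of freedom) and eBayes, and p-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison. Errors of log2 fold changes are limma's moderated standard errors. The 6 comparisons were β-floxed minus β-heterozygous and double minus α-null, each within 1 block of deposited samples, the interaction of these effects, and α-null minus β-heterozygous, double minus β-heterozygous and double minus β-floxed, each across the blocks. Before the data were examined, 30 gene lists were fixed with 746 gene names, of which 56 had no match. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of 1 comparison, and again with an estimated correlation, under which 0 lists passed in every comparison (between 1 and 4 did so at an unadjusted p under 0.05). Members were also counted with p-values adjusted over the list alone. A list's call by camera says nothing of members that moved against its direction, which are counted beside it.

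Genes were named by a rule set before the data were examined. It took Gsk3a and Gsk3b, the 10 largest increases and 10 largest decreases among genes that passed and whose groups did not overlap in any array (5 each for the interaction, without the overlap condition), and up to 4 members of smallest p from each list that passed or had a member passing. Gene models without a name were skipped. The rule gave 753 pairs of gene and comparison, of which 269 are reported. That part was picked after the values were seen, so it is not a random part of the whole, and the stability of all 753 is given with the alternatives.

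The fit was tested on simulated arrays of 14751 genes. Each gene had its mean over all arrays, 1 pooled spread for every group and independent noise. In these, 200 genes had a known change and the erythroid list was shifted by 2 log2 units. Unequal spreads between groups, correlated genes and changes in as many genes as in the data were not simulated. The following shares hold only under those conditions. For β-floxed against β-heterozygous, 52% of genes changed by 1 log2 unit and 88% of those changed by 2 were called. For double against α-null the shares were 70% and 92%, and for the interaction 8% and 66%. Principal components and control probe sets were computed with Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

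Alternatives fixed before the data were examined were no filter and a stricter filter (50th percentile), quantile normalization, median centring, eBayes with trend and robust options, array weights, the replicate number as a block, only the groups compared, the mean of a gene's probe sets, each array left out, other thresholds and the estimated correlation. After the data were seen, 2 more were added: α-null replicate 1 alone in its group, and the actin 3′ minus 5′ difference as a covariate. No column of sample values was left unused. Controls served only for checks of array quality.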

Results

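Gene expression was measured in lineage-negative, Sca1-positive, cKit-positive cells, the marrow fraction that holds hematopoietic stem and early progenitor cells. The cells were sorted from recipient mice that had been engrafted with marrow carrying different dosages of glycogen synthase kinase 3, a serine/threonine kinase encoded by the paralogs Gsk3a and Gsk3b. The donor cells carried a tamoxifen-inducible Cre recombinase, and floxed Gsk3b was to be removed after transplantation by 3 injections of tamoxifen. The study's title asks what stepwise loss of the kinase does to blood stem cells on the way to acute leukemia. The 10 samples, each on 1 array, fell into 4 groups: arrays labelled β-heterozygous (α intact, 1 floxed β allele, n = 2), arrays labelled β-floxed (α intact, both β alleles floxed, n = 2), arrays labelled α-null (β intact, n = 3) and arrays labelled double (α-null with both β alleles floxed, n = 3). The α-intact and the α-null arrays were deposited as separate blocks, so a comparison across α genotype could not be told apart from a comparison of blocks. Array medians lay between 7.22 and 7.39 log2 units and interquartile ranges between 2.25 and 2.97, and the number of arrays limited the precision. These ranges were narrowest in the β-heterozygous arrays (2.25 and 2.41). They were 2.76 and 2.42 in the β-floxed, 2.84 to 2.97 in the α-null and 2.72 to 2.88 in the double arrays.

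The targeted genes were examined first. Gsk3a, read by 1 probe set, lay at 11.10 ± 0.29 (SD, n = 2) in arrays labelled β-heterozygous, 11.54 ± 0.07 (n = 2) in β-floxed, 11.03 ± 0.36 (n = 3) in α-null and 9.08 ± 0.23 (n = 3) in double arrays. Against the label, it did not pass between arrays labelled α-null and β-heterozygous (log2 fold change -0.07 ± 0.24, SE), although it was lower by that comparison with quantile normalization (-0.84, adjusted p = 0.0146). It was 3.88-fold lower in the arrays labelled double than in those labelled α-null (limma adjusted p = 4.19e-05). Where this probe set lies relative to the disrupted part of Gsk3a was not known here. Gsk3b was read by 6 probe sets, and with all arrays its gene-level value did not pass in any comparison. Without β-floxed replicate 2 it passed as higher in the arrays labelled β-floxed than in those labelled β-heterozygous (1.32, adjusted p = 0.00473). In arrays labelled double against β-floxed it passed as lower without that array (-0.99, 0.0144) and as higher without β-floxed replicate 1 (0.76, 0.0406). The one brightest on average, which stood for the gene, lay at 9.66 ± 0.59 in β-heterozygous, 10.11 ± 1.24 in β-floxed, 9.79 ± 0.12 in α-null and from 9.94 to 10.04 in double arrays. A second stood at 8.93 ± 0.32, 8.73 ± 0.56, 9.89 ± 0.13 and 10.24 ± 0.18 in these groups, and the group means of the other 4 lay between 7.34 and 8.58. In arrays labelled double against α-null, these 4 stood at 7.66 against 7.34, 8.58 against 8.24, 8.4 against 7.7, and 8.13 ± 0.26 against 8.23 ± 0.25. Against the label, none of the 6 was lower in the double arrays beyond its spread. A probe set outside the deleted exon checks nothing about its loss, and the position of these 6 was not known here. Groups are therefore named by label throughout.

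Sex-linked genes did not match one label either, since all samples were labelled male. Xist, the X-inactivation RNA, reached 12.99 and 13.47 in arrays labelled α-null replicates 2 and 3, where the Y-linked gene Eif2s3y stood at 4.91 and 5.02. In α-null replicate 1 they stood at 8.50 and 10.33, and in the double arrays Xist lay between 8.50 and 8.80 with Eif2s3y between 10.91 and 11.21. All 4 α-intact arrays held both, with Xist from 9.90 to 12.69 and Eif2s3y from 9.28 to 10.29. Control probe sets differed between the blocks too. The actin 3′ minus 5′ difference, a measure of how far transcripts were copied from their 3′ end, was 2.27 to 3.39 in the α-intact arrays and 1.21 to 1.69 in the α-null and double arrays. Hybridization controls averaged 11.56 to 12.58 in the first block and 10.55 to 11.08 in the second.

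**Figure D1:**
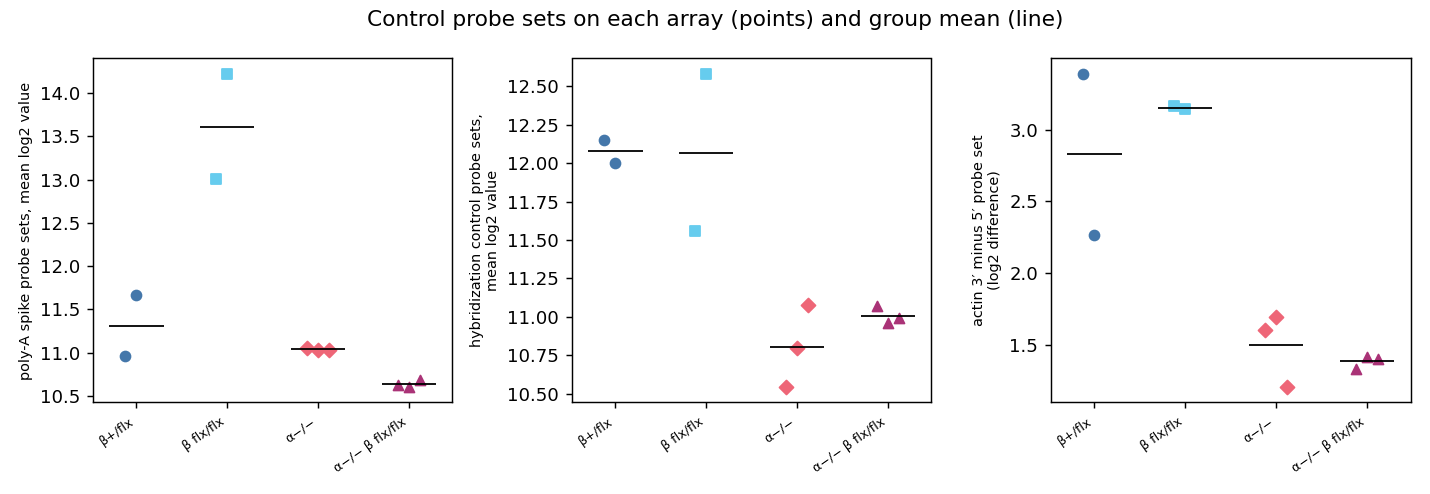
Control probe sets by group, each point 1 array and each line the group mean, with mean log2 value of the poly-A spikes (left), mean log2 value of the hybridization controls (middle) and actin 3′ minus 5′ log2 difference (right) on the vertical axes. Poly-A spikes read 13.01 and 14.22 in the arrays labelled β-floxed and 10.60 to 11.67 elsewhere, and the actin difference was 2.27 to 3.39 in the α-intact arrays.

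The first component, with 50.5% of the variance, set the 3 arrays labelled double (scores 84.9 to 93.0) apart from the other 7 (-48.4 to -32.9). The second, with 29.1%, ran from the arrays labelled β-heterozygous (-84.1 and -51.3) to those labelled α-null (41.9 to 62.4), with the β-floxed pair between them (-29.3 and 8.66). On the third, with 11.5%, β-floxed replicate 1 stood alone at 77.9, against 14.0 for replicate 2. Across genes, arrays labelled double correlated with each other at 0.994 to 0.996, those labelled α-null at 0.979 to 0.987, the β-heterozygous pair at 0.950 and the β-floxed pair at 0.897.

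**Figure D2:**
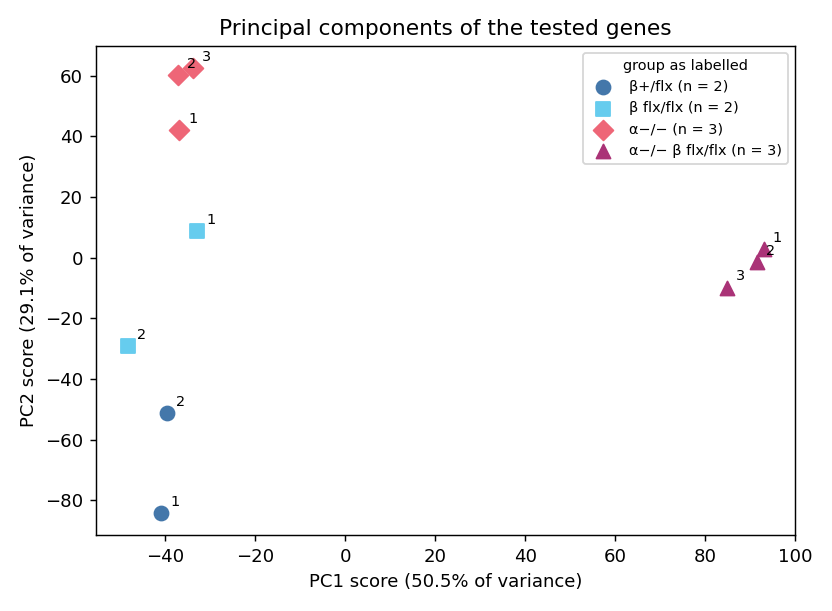
Scores of the 10 arrays on the first (horizontal axis, 50.5% of variance) and second (vertical axis, 29.1%) principal component of the tested genes, with colour and symbol for the group as labelled and digits for the replicate. The 3 arrays labelled double lie between 84.9 and 93.0 on the horizontal axis, and all others below 0.

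The first comparison asked what loss of β does with α intact, as arrays labelled β-floxed (n = 2) against β-heterozygous (n = 2). Poly-A spike controls read 13.01 and 14.22 in the β-floxed arrays, and 10.96 and 11.67 in the β-heterozygous arrays. A technical difference between these groups could therefore not be told apart from the genotype. Neutrophil genes were lower in the β-floxed arrays. Lcn2, the siderophore-binding lipocalin of neutrophil granules, was lower (log2 fold change -6.84 ± 0.96, SE), as were the neutrophil surface protein Cd177 (-6.36 ± 0.47) and S100a9 (-5.75 ± 1.01), a calcium-binding protein abundant in neutrophils. Procr (4.19 ± 0.63), the endothelial protein C receptor used to mark stem cells, and Vwf (3.89 ± 0.65), von Willebrand factor, were higher. The errors come from a spread shared by all groups. The median SD of a gene was 0.23 in β-heterozygous and 0.29 in β-floxed arrays, against 0.16 in α-null and 0.11 in double arrays. The errors of this comparison may therefore be too small. Lcn2 read 5.60 and 9.50 in the β-floxed pair. The sizes rested on which of the β-floxed arrays was used. Without replicate 1 the values were -4.89, -5.65 and -3.71 for the neutrophil genes and 2.83 and 2.54 for Procr and Vwf, and without replicate 2 they were -8.79, -7.07, -7.78, 5.55 and 5.24. Of 14751 genes tested with limma, 2701 passed an adjusted p of 0.05, with 2226 higher and 475 lower in the β-floxed arrays, and 1678 of them changed at least 2-fold.

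The largest increases were those of Bex1 (5.91 ± 0.95), the cathepsin inhibitor-like genes Ctla2b (5.04 ± 0.44) and Ctla2a (3.89 ± 0.35), the immediate early nuclear receptor Nr4a2 (4.51 ± 0.80), Procr, the terminal transferase Dntt (4.09 ± 0.99), the transglutaminase Tgm2 (4.00 ± 0.69), Vwf, platelet factor Pf4 (3.84 ± 0.52) and Afp (3.69 ± 0.47). Dntt passed with an adjusted p of 0.0202 and lost it without β-heterozygous replicate 1 (0.118) or without β-floxed replicate 1 (0.0813). The largest decreases after Lcn2, Cd177 and S100a9 were Slfn4 (-5.71 ± 0.56), Chil3 (-5.68 ± 1.03), the NADPH oxidase subunit Cybb (-5.43 ± 0.67), the granule proteins Ltf (-5.32 ± 0.57) and Camp (-5.21 ± 0.72), Ifitm6 (-5.32 ± 0.32) and Wfdc21 (-5.15 ± 0.52). Of the genes reported as passing in this comparison, 27 moved by over 1.5-fold when 1 array was left out and 27 did not. Without β-floxed replicate 1 and without replicate 2, the increases stood at 3.95 and 7.87 for Bex1, 4.29 and 5.79 for Ctla2b, 2.78 and 6.23 for Nr4a2, 2.66 and 5.51 for Dntt, 2.60 and 5.41 for Tgm2, 3.13 and 4.55 for Pf4, and 2.91 and 4.46 for Afp. The decreases stood at -4.70 and -6.73 for Slfn4, -3.45 and -7.92 for Chil3, -4.01 and -6.86 for Cybb, -4.34 and -6.30 for Ltf, -3.92 and -6.51 for Camp, and -4.32 and -5.98 for Wfdc21.

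By list, 16 of 22 granulocyte genes fell, 0 rose and 6 did not pass (19 fell adjusted over the list alone), with a median of -2.43 against 0.15 for all tested genes (-3.93 without β-floxed replicate 2). Camera gave this list an adjusted p of 1.19e-20, and an adjusted p = 0.543 with an estimated correlation. Mmp9 (-4.40 ± 0.28), Mmp8 (-4.62 ± 0.42; -3.99 without β-floxed replicate 1 and -5.26 without replicate 2) and Anxa1 (-2.15 ± 0.20) were among its members. Of 27 long-term stem cell markers, 12 rose and 15 did not pass (23 rose adjusted over the list alone), including Rbpms (3.25 ± 0.47, or 2.29 and 4.21 without those arrays) and Sult1a1 (1.76 ± 0.22). Their median change was 1.64, but 0.56 without β-floxed replicate 1 and 2.79 without replicate 2, and the median deviation of the list was 1.95 in replicate 1 and 0.13 in replicate 2. Camera gave the stem cell markers an adjusted p of 9.64e-06, and an adjusted p = 0.736 with an estimated correlation. The immediate early and heat shock genes had 16 of 31 higher and 15 not passing (16 adjusted over the list alone), with Egr2 at 2.09 ± 0.21, Egr1 at 1.58 ± 0.20 and the chaperone Dnajb1 at 1.68 ± 0.22. Camera gave the immediate early and heat shock genes an adjusted p of 9.64e-06, and an adjusted p = 0.736 with an estimated correlation. Among 71 oxidative phosphorylation genes, 29 rose and 42 did not pass (36 adjusted over the list alone), as Atp5e did by 1.60 ± 0.21 and Ndufb2 by 1.53 ± 0.19. Camera gave the oxidative phosphorylation genes an adjusted p of 6.82e-07, and an adjusted p = 0.791 with an estimated correlation. Ribosomal protein genes rose in 17 of 44 cases with 27 not passing (23 adjusted over the list alone), among them Rpl14 (1.65 ± 0.25) and Rpl37 (1.17 ± 0.16). Camera gave the ribosomal protein genes an adjusted p of 9.64e-06, and an adjusted p = 0.736 with an estimated correlation.

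Of 22 erythroid genes 8 rose and 14 did not pass (8 adjusted over the list alone), including the GATA1 cofactor gene Zfpm1 (3.47 ± 0.35, or 2.87 without β-floxed replicate 1 and 4.06 without replicate 2) and Hemgn (2.79 ± 0.32). Camera gave the erythroid genes an adjusted p of 0.0165, and an adjusted p = 0.736 with an estimated correlation. Of 16 lymphoid-primed progenitor genes 6 rose and 10 did not pass (6 adjusted over the list alone), with the transcription factor Bcl11a at 2.44 ± 0.27 and the progenitor antigen Cd34 at 2.09 ± 0.33. Camera gave the lymphoid-primed genes an adjusted p of 0.0181, and an adjusted p = 0.736 with an estimated correlation. Of 18 B cell genes 7 rose and 11 did not pass (8 higher and 2 lower adjusted over the list alone), without a camera call (adjusted p = 0.359). Of 24 monocyte, macrophage and dendritic cell genes 3 rose, 3 fell and 18 did not pass (4 and 4 adjusted over the list alone), and lysozyme Lyz2 (-2.60 ± 0.24) and the endotoxin co-receptor Cd14 (-2.04 ± 0.21) were lower. Camera gave the monocyte, macrophage and dendritic cell genes an adjusted p of 0.0185, and an adjusted p = 0.791 with an estimated correlation. That list's direction turned without β-floxed replicate 1, where its median was 0.53. Camera also passed the leukemia-associated HOX/MEIS genes as higher (9 of 22 rose, 13 adjusted over the list alone, adjusted p = 0.0181, and adjusted p = 0.736 with an estimated correlation). It passed the MYC target genes as higher too (9 of 32 rose, 11 over the list alone, adjusted p = 0.00279, and adjusted p = 0.791 with an estimated correlation). The T and NK cell genes passed camera as lower (median -0.28, adjusted p = 0.0181, and adjusted p = 0.791 with an estimated correlation). Of these 20 genes, 0 passed in limma and 2 did at an unadjusted p under 0.05. In lists without a camera call, the cell cycle inhibitor Cdkn1a (2.48 ± 0.43) and Sesn1 (2.20 ± 0.38), both p53 targets, were higher, and the cytokine Il6 (-3.23 ± 0.49), the decoy receptor Il1r2 (-3.70 ± 0.19) and liver glycogen phosphorylase Pygl (-2.44 ± 0.24) were lower. Cdkn1a stood at 1.62 and Sesn1 at 1.44 without β-floxed replicate 1, and at 3.35 and 2.97 without replicate 2. Il6 stood at -2.59 without β-heterozygous replicate 1 and -3.87 without replicate 2.

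The following calls of this comparison were lost under other settings. The leukemia-associated homeobox gene Meis1 (3.66 ± 0.70), Car2 (3.22 ± 0.59), Erg (2.27 ± 0.43), the class II gene H2-Ab1 (2.22 ± 0.47), Lmo2 (1.53 ± 0.30), Myc (1.22 ± 0.23) and Gnl3 (0.96 ± 0.20) passed, and without β-heterozygous replicate 1 none of these 7 did (adjusted p from 0.0505 to 0.0806). Without β-floxed replicate 1 and without replicate 2, Meis1 stood at 2.26 and 5.06, Car2 at 1.94 and 4.50 and H2-Ab1 at 3.09 and 1.34. Cyclin Ccnd1 (0.79 ± 0.21) lost its call without β-heterozygous replicate 1 (0.15) or any one of the double arrays (0.0527 to 0.0575), and glycogen synthase Gys1 (-0.99 ± 0.26) without β-heterozygous replicate 2 (0.109), β-floxed replicate 1 (0.123) or any one of the double arrays (0.053 to 0.0554). The ribosome biogenesis gene Wdr43 (0.98 ± 0.19) lost it with quantile normalization (0.56, adjusted p = 0.0538), as did Gnl3 (0.52, 0.0508). The immunoglobulin gene Ighm went from 3.05 ± 0.20 to 0.52 with the mean of its probe sets and lost its call (0.163). Gys1 also lost it with α-null replicate 1 alone (0.0729). Quantile normalization ended the oxidative phosphorylation call (median from 0.61 to 0.17, adjusted p = 0.0573) and those of the HOX/MEIS, macrophage, and T and NK cell genes (0.0598 each) and MYC targets (0.204). The HOX/MEIS and lymphoid-primed calls were lost with the stricter filter (0.107 and 0.0649) and with the actin difference in the fit (0.1 and 0.16). The lymphoid-primed call was also lost with the mean of the probe sets (0.151), and the macrophage call with no filter (0.0503). Of the lists, the erythroid, lymphoid-primed and HOX/MEIS calls were lost without β-heterozygous replicate 2 (0.126, 0.203 and 0.2) and the first of these also without β-floxed replicate 2 (0.153), as was the lymphoid-primed call (0.0695). The MYC target call was lost without β-heterozygous replicate 1 (0.334) or β-floxed replicate 2 (0.108), and the T and NK cell and macrophage calls without β-heterozygous replicate 1 (0.0954 and 0.095) or β-floxed replicate 1 (0.25 and 0.41).

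The number of genes passing fell to 59 when limma was fitted to these 4 arrays alone, where Lcn2 (adjusted p = 0.058), S100a9 (0.1), Procr (0.0933) and Vwf (0.106) did not pass, and to 270 with array weights. Of the genes reported here, 37 lost the call with these arrays alone and 17 with weights. It was 968 without β-heterozygous replicate 1, 6011 without β-floxed replicate 2, 1771 without double replicate 2 and 1623 with α-null replicate 1 alone in its group, and quantile normalization moved the share of calls that were higher from 82.4% to 63.9%.

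The comparison of arrays labelled double (n = 3) with arrays labelled α-null (n = 3) asked what loss of β does when α is absent by label, within 1 block. The macrophage metalloelastase Mmp12 (log2 fold change 9.28 ± 0.14, SE), the collagenase Mmp13 (8.92 ± 0.16) and the lysosomal proton pump subunit Atp6v0d2 (8.33 ± 0.14) were higher in the arrays labelled double. These 3 lay under the filter level of 6.39 in all arrays labelled α-null, from 5.06 to 5.33, 4.80 to 5.20 and 5.58 to 5.77, so the size of the change depends on how low the arrays can read. Myeloperoxidase Mpo, made by granulocyte-monocyte progenitors, was 195-fold lower (-7.61 ± 0.30), and the anaphase activator Cdc20 63.3-fold lower (-5.98 ± 0.20). Of 14751 genes, 5561 passed in limma, 2387 higher and 3174 lower, and 3438 of these changed at least 2-fold.

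After those, the largest increases were Gpnmb (7.93 ± 0.24), the scavenger receptor Cd36 (7.51 ± 0.27), the C-type lectin Clec4n (7.37 ± 0.24), the chemokines Ccl2 (6.79 ± 0.26) and Cxcl3 (6.50 ± 0.28), the lipase Pla2g7 (6.70 ± 0.27) and Bst1 (6.69 ± 0.32). The largest decreases were Mpo, the neutrophil serine proteases Prtn3 (-7.12 ± 0.37) and Ctsg (-6.43 ± 0.74), the water channel Aqp1 (-6.61 ± 0.17), Hemgn (-6.36 ± 0.26), carbonic anhydrase Car1 (-6.30 ± 0.43), the Rh-associated glycoprotein Rhag (-6.21 ± 0.27), the amino acid transporter Slc38a5 (-6.17 ± 0.14), eosinophil major basic protein Prg2 (-6.13 ± 0.53) and Cdc20. The tested genes had a median of -0.02.

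Genes of cell division were lower as groups. All 35 mitosis genes fell (35 adjusted over the list alone, median -3.74), such as Ccnb2 (-5.21 ± 0.21), Kif20a (-4.71 ± 0.18) and Cenpa (-4.04 ± 0.17). Camera gave the mitosis genes an adjusted p of 1.8e-24, and an adjusted p = 0.161 with an estimated correlation. Of 40 DNA replication genes 38 fell and 2 did not pass (39 adjusted over the list alone, median -3.11), with Cdc6 at -5.92 ± 0.22, Mcm5 at -5.24 ± 0.20 and Mcm7 at -4.88 ± 0.17. Camera gave the DNA replication genes an adjusted p of 2.61e-24, and an adjusted p = 0.161 with an estimated correlation. Ribosomal protein genes fell in 35 of 44 cases and 9 did not pass (36 fell and 1 rose adjusted over the list alone), Rpl14 by -2.60 ± 0.20. Camera gave the ribosomal protein genes an adjusted p of 2.77e-09, and an adjusted p = 0.366 with an estimated correlation. MYC target genes fell in 21 of 32 cases and 11 did not pass (22 adjusted over the list alone), as did Cad (-3.25 ± 0.23), while Myc itself stood at -2.96 ± 0.19. Camera gave the MYC target genes an adjusted p of 1.91e-06, and an adjusted p = 0.569 with an estimated correlation. Of 71 oxidative phosphorylation genes 19 fell, Ndufs8 among them (-1.30 ± 0.19), and 52 did not pass (15 adjusted over the list alone). Camera gave the oxidative phosphorylation genes an adjusted p of 0.0102, and an adjusted p = 0.659 with an estimated correlation. With α-null replicate 1 alone, the adjusted p of this last list was 0.191.

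Blood lineage genes moved in different directions. Erythroid genes fell in 20 of 22 cases and 2 did not pass (20 adjusted over the list alone, median -3.98), including the anion exchanger Slc4a1 (-5.94 ± 0.22), the Rhesus gene Rhd (-5.37 ± 0.18) and Ermap (-5.02 ± 0.16). Camera gave the erythroid genes an adjusted p of 4.03e-14, and an adjusted p = 0.0623 with an estimated correlation. Among monocyte, macrophage and dendritic cell genes 10 of 24 rose, 2 fell and 12 did not pass (11 and 2 adjusted over the list alone, median 1.11). Camera gave the monocyte, macrophage and dendritic cell genes an adjusted p of 0.000995, and an adjusted p = 0.552 with an estimated correlation. The macrophage markers Cd68 (4.69 ± 0.28) and Adgre1 (4.54 ± 0.18), the integrin Itgax (3.85 ± 0.36) and Lyz2 (2.01 ± 0.20) were higher. Granulocyte genes fell in 12 of 22 cases, rose in 5 and did not pass in 5 (14 and 5 adjusted over the list alone, median -1.435), without a camera call (adjusted p = 0.0789). Mpo was among those that fell, and Itgam (4.75 ± 0.19) and Mmp8 (5.12 ± 0.34) were among the fewer that rose. Lymphoid-primed progenitor genes fell in 10 of 16 cases, rose in 3 and did not pass in 3 (10 and 3 adjusted over the list alone), with Cd34 at -4.70 ± 0.27 and the interleukin 7 receptor Il7r at 5.03 ± 0.37. The α-null replicate 2 array stood apart in lymphoid genes. Its median deviation was 1.39 for the lymphoid-primed list (0.37 and 0.48 in replicates 1 and 3) and 1.25 for the T and NK cell list (-0.23 and 0.02), and the T cell surface gene Thy1 read 13.71 there against 8.27 and 9.75. Camera gave the lymphoid-primed genes an adjusted p of 0.0126, and an adjusted p = 0.535 with an estimated correlation. Of 22 leukemia-associated HOX/MEIS genes 11 fell, 1 rose and 10 did not pass (11 and 1 adjusted over the list alone), with Myb at -5.31 ± 0.19 and Hoxa9 at -3.73 ± 0.40. Camera gave the HOX/MEIS genes an adjusted p of 0.0365, and an adjusted p = 0.569 with an estimated correlation. The HOX/MEIS call was lost without α-null replicate 1 (0.0775), without either β-heterozygous replicate (0.0546 each), with the stricter filter (0.0953) and with the actin difference in the fit (0.0664). Stromal and endothelial genes fell in 5 of 15 cases, rose in 2 and did not pass in 8 (6 and 2 adjusted over the list alone), without a camera call (adjusted p = 0.274), and Col1a1 read 7.06 to 7.29 in the arrays labelled double against 10.42 to 12.06. Stem cell markers were split, 5 higher and 6 lower of 27, among them Procr (5.70 ± 0.52), the cell cycle inhibitor Cdkn1c (4.48 ± 0.21) and Gata2 (-2.14 ± 0.24), and did not pass camera (adjusted p = 0.89).

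Interferon-stimulated genes rose in 21 of 36 cases and 15 did not pass (21 adjusted over the list alone), with Ifi204 at 5.05 ± 0.28, Ifit1 at 2.56 ± 0.32 and Oas1a at 2.25 ± 0.27. Camera gave the interferon-stimulated genes an adjusted p of 1.91e-06, and an adjusted p = 0.535 with an estimated correlation. Inflammatory genes rose in 13 of 24 cases, fell in 2 and did not pass in 9 (16 and 4 adjusted over the list alone), with Il1a at 3.51 ± 0.17. Camera gave the inflammatory genes an adjusted p of 0.000306, and an adjusted p = 0.161 with an estimated correlation. Cholesterol biosynthesis genes rose in 10 of 22 cases, fell in 1 and did not pass in 11 (11 and 1 adjusted over the list alone), including the enzymes Msmo1 (3.01 ± 0.16), Mvd (1.94 ± 0.21) and Hmgcs1 (1.62 ± 0.21). Camera gave the cholesterol biosynthesis genes an adjusted p of 0.0102, and an adjusted p = 0.555 with an estimated correlation. Targets of p53 rose in 12 of 23 cases, fell in 4 and did not pass in 7 (12 and 4 adjusted over the list alone), as Zmat3 (2.87 ± 0.18) and Phlda3 (2.06 ± 0.19). Camera gave the p53 targets an adjusted p of 0.0128, and an adjusted p = 0.535 with an estimated correlation. Immediate early and heat shock genes fell in 14 of 31 cases, rose in 5 and did not pass in 12 (15 and 5 adjusted over the list alone), with Egr1 at -4.18 ± 0.17, Fosb at -3.82 ± 0.23 and Ier2 at -3.75 ± 0.19. Camera gave the immediate early and heat shock genes an adjusted p of 0.0236, and an adjusted p = 0.61 with an estimated correlation, and the stricter filter ended the call (0.0556). Wnt/β-catenin target genes, 4 higher and 5 lower of 19, did not pass camera (adjusted p = 0.842), although Id2 (3.51 ± 0.30) and Jag1 (3.24 ± 0.48) were higher. Heme oxygenase Hmox1 (4.17 ± 0.32) and Fabp4 (6.01 ± 0.35) were higher too, in lists without a camera call. The Y-linked genes Eif2s3y (4.33 ± 1.15) and Kdm5d (2.39 ± 0.67) passed, and did not without α-null replicate 2 (adjusted p = 0.0507 and 0.0683) or replicate 3 (0.0575 and 0.0746), nor did Kdm5d without double replicate 2 (0.0508). With α-null replicate 1 alone they stood at 0.76 and 0.42 (0.224 and 0.622), and without that array at 6.12 and 3.38.

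The count was 8464 with array weights and 2885 with α-null replicate 1 alone, the array whose sex-linked genes fitted its label.

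**Figure D3:**
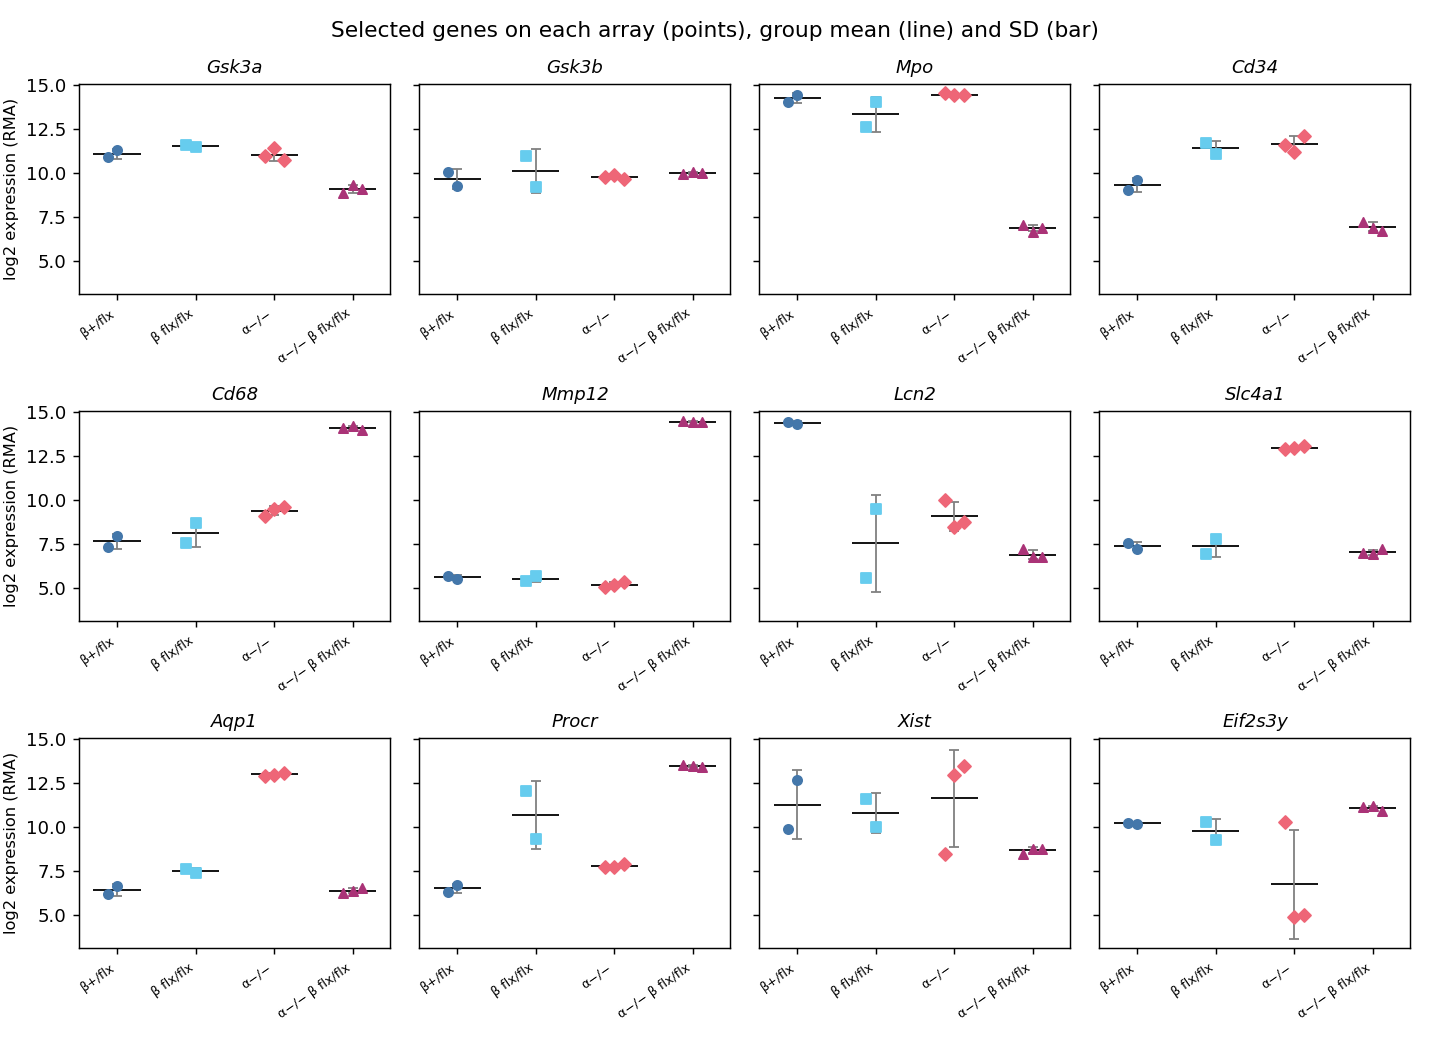
Log2 expression (vertical axes) of 12 genes on each array (points) by group as labelled, with the group mean (line) and SD (bar). Mmp12 lies above 14.3 in the 3 arrays labelled double and below 5.8 elsewhere, Aqp1 is near 13.0 in those labelled α-null, and Lcn2 is near 14.4 in those labelled β-heterozygous.

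Whether the β effect differed between α backgrounds was tested as the interaction. Genes of the neutrophil and macrophage lines led it upward: Mmp8 (log2 difference of the effects 9.75 ± 0.54, SE), Mmp12 (9.35 ± 0.23), Mmp13 (8.98 ± 0.25), Chil3 (8.90 ± 1.33) and Cybb (8.73 ± 0.86). Mmp12 and Mmp13 lay under 6.39 in all arrays but those labelled double, so the size of their difference depends on how low the arrays can read. Downward it was led by Hemgn (-9.15 ± 0.41), the retinaldehyde dehydrogenase Aldh1a1 (-8.96 ± 0.49), Dntt (-8.43 ± 1.28), Car2 (-7.76 ± 0.77) and Aqp1 (-7.68 ± 0.26). Without β-floxed replicate 1 and without replicate 2, Mmp8 stood at 9.12 and 10.38, Chil3 at 6.67 and 11.14, Cybb at 7.30 and 10.16, Dntt at -7.00 and -9.85 and Car2 at -6.48 and -9.04, and Dntt stood at -7.49 without α-null replicate 2. Of 14751 genes 5464 passed in limma, 1680 with a higher and 3784 with a lower β effect in the α-null background, and the median of all tested genes was -0.10. The baselines differ, since the α-null baseline kept both β alleles and the α-intact baseline 1.

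Erythroid genes had a lower β effect in 19 of 22 cases with 3 not passing (19 adjusted over the list alone, median -4.96). Camera gave the erythroid genes an adjusted p of 5.2e-12, and an adjusted p = 0.0945 with an estimated correlation. Mitosis genes did so in 32 of 35 cases with 3 not passing (34 adjusted over the list alone), and DNA replication genes in 38 of 40 with 2 not passing (38 adjusted over the list alone), with Mcm5 at -5.68 ± 0.32 and Mcm7 at -5.53 ± 0.28. Camera gave the mitosis genes an adjusted p of 7.97e-18, and an adjusted p = 0.285 with an estimated correlation. Camera gave the DNA replication genes an adjusted p of 7.97e-18, and an adjusted p = 0.285 with an estimated correlation. Ribosomal protein genes were lower in 38 of 44 cases with 6 not passing (38 lower and 1 higher adjusted over the list alone, with Rpl14 -4.25 ± 0.32). Camera gave the ribosomal protein genes an adjusted p of 1.6e-09, and an adjusted p = 0.351 with an estimated correlation. Granulocyte genes had a higher β effect in 13 of 22 cases, a lower one in 4 and did not pass in 5 (13 and 5 adjusted over the list alone). Their median was below 0 in both β comparisons, -2.43 with α intact and -1.435 with α absent by label, so the list as a whole did not rise. Monocyte, macrophage and dendritic cell genes had a higher β effect in 10 of 24 cases, a lower one in 2 and did not pass in 12 (10 and 2 adjusted over the list alone), with Adgre1 at 4.84 ± 0.28 and Lyz2 at 4.61 ± 0.31. Camera gave the granulocyte genes an adjusted p of 0.000785, and an adjusted p = 0.569 with an estimated correlation. Camera gave the monocyte, macrophage and dendritic cell genes an adjusted p of 0.000657, and an adjusted p = 0.537 with an estimated correlation. MYC target genes had a lower β effect in 25 of 32 cases with 7 not passing (25 adjusted over the list alone), and camera gave an adjusted p of 6.36e-07, and an adjusted p = 0.569 with an estimated correlation. Oxidative phosphorylation genes did in 41 of 71 cases with 30 not passing (47 lower and 1 higher adjusted over the list alone), and camera gave an adjusted p of 2.59e-06, and an adjusted p = 0.606 with an estimated correlation. Immediate early and heat shock genes were lower in 17 of 31 cases, higher in 3 and not passing in 11 (18 and 3 adjusted over the list alone), and camera gave an adjusted p of 0.000525, and an adjusted p = 0.537 with an estimated correlation. Interferon-stimulated genes were higher in 12 of 36 cases, lower in 2 and not passing in 22 (12 and 2 adjusted over the list alone), and camera gave an adjusted p of 0.000303, and an adjusted p = 0.569 with an estimated correlation. Inflammatory genes were higher in 9 of 24 cases with 15 not passing (9 adjusted over the list alone), and camera gave an adjusted p of 0.000657, and an adjusted p = 0.271 with an estimated correlation. Single genes with a strongly different β effect were Msmo1 (4.00 ± 0.25), Myb (-5.95 ± 0.30), Egr1 (-5.76 ± 0.26), Erg (-4.84 ± 0.56), Myc (-4.18 ± 0.30), Cad (-3.88 ± 0.36) and Ndufb2 (-2.24 ± 0.25). Across the 14751 genes the β effects correlated negatively (Pearson r = -0.166, Spearman rho = -0.24), genes not being independent replicates. Of 2226 genes higher in the β-floxed than in the β-heterozygous arrays, 1017 were lower in the double than in the α-null arrays, where independent lists would share 479.0. Those higher in both comparisons numbered 337, against 360.2. Camera passed 15 lists, of which those of stem cell markers, HOX/MEIS, lymphoid-primed and cholesterol biosynthesis genes (adjusted p = 0.0331, 0.00814, 0.0134 and 0.0331) did not pass without β-heterozygous replicate 2 (0.112, 0.0507, 0.0936 and 0.112). With an estimated correlation these 4 had adjusted p = 0.734, 0.537, 0.537 and 0.569. Stem cell markers were lower in 11 of 27 cases and higher in 2, HOX/MEIS genes lower in 11 of 22, lymphoid-primed genes lower in 10 of 16 and higher in 3, and cholesterol genes higher in 6 of 22 and lower in 2. Without β-floxed replicate 1 and without replicate 2, the median was -0.72 and -2.97 for stem cell markers (-1.81 with all arrays), 1.87 and 4.13 for granulocyte genes (3.19), and 0.29 and 2.03 for monocyte, macrophage and dendritic cell genes (1.35). Stem cell markers also failed without β-heterozygous replicate 1 (0.0669), and cholesterol genes without β-floxed replicate 1 (0.0553) or α-null replicate 1 (0.0554). The stem cell call was also lost with the stricter filter (0.177), median centring (0.0577) and the actin difference in the fit (0.0974), the cholesterol call with no filter (0.0528), the mean of the probe sets (0.244) and the actin difference (0.0974), and the lymphoid-primed call with that mean (0.0637) and the actin difference (0.0859).

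The count of the interaction was 3331 with α-null replicate 1 alone.

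The comparison of arrays labelled α-null (n = 3) with arrays labelled β-heterozygous (n = 2) asked what loss of α does, and it crossed the blocks. By label the groups also differed at β, since the β-heterozygous arrays had a floxed β allele and the α-null arrays none. Loss of α, the floxed β allele and the block could not be told apart. Erythroid genes were higher in the arrays labelled α-null. Aqp1 was 94.0-fold higher (log2 fold change 6.55 ± 0.18, SE), Hemgn 88.8-fold (6.47 ± 0.29), Slc4a1 48.3-fold (5.59 ± 0.24) and Car1 46.4-fold (5.54 ± 0.48). The neutrophil genes Lcn2 (-5.29 ± 0.88) and Cd177 (-5.23 ± 0.43) were lower. Of 14751 genes 7665 passed in limma, 5252 higher and 2413 lower, and 4136 changed at least 2-fold.

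The other largest increases were Slc38a5 (5.86 ± 0.15), Rhag (5.57 ± 0.30), Car2 (5.48 ± 0.54), the sphingosine 1-phosphate transporter Mfsd2b (5.39 ± 0.19), Cldn13 (5.26 ± 0.25) and Aldh1a1 (5.13 ± 0.35). The other largest decreases were Slfn4 (-6.27 ± 0.52), S100a9 (-5.41 ± 0.93), Lrg1 (-5.05 ± 0.28), the formyl peptide receptor Fpr2 (-5.00 ± 0.36), Ifitm6 (-4.75 ± 0.29), Camp (-4.72 ± 0.66), Il1r2 (-4.66 ± 0.17) and Mmp8 (-4.54 ± 0.38).

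By list, 20 of 22 erythroid genes rose and 2 did not pass (20 adjusted over the list alone, median 3.68 against 0.20 for all tested genes), with Rhd at 4.81 ± 0.21 and Ermap at 4.52 ± 0.18. Camera gave the erythroid genes an adjusted p of 4.66e-10, and an adjusted p = 0.131 with an estimated correlation. Some markers of other cell types were higher too, in lists without a camera call. Of 16 lymphoid-primed genes 9 rose and 7 did not pass (9 adjusted over the list alone, camera adjusted p = 0.0596), and of 15 stromal and endothelial genes 5 rose and 10 did not pass (5 adjusted over the list alone, 0.775). The collagen gene Col1a1 read 10.42 to 12.06 in the arrays labelled α-null and 7.91 and 7.96 in those labelled β-heterozygous, and Col1a2 10.97 to 12.67 against 8.04 and 8.20. Granulocyte genes fell in 15 of 22 cases, rose in 1 and did not pass in 6 (15 and 1 adjusted over the list alone), Mmp9 by -4.25 ± 0.26. Camera gave the granulocyte genes an adjusted p of 3.57e-07, and an adjusted p = 0.699 with an estimated correlation. Of 40 DNA replication genes 39 rose and 1 fell (39 and 1 adjusted over the list alone), Pole2 by 2.11 ± 0.20 and Rfc4 by 1.81 ± 0.18. Camera gave the DNA replication genes an adjusted p of 3.63e-09, and an adjusted p = 0.699 with an estimated correlation. Mitosis genes rose in 27 of 35 cases and 8 did not pass (27 adjusted over the list alone), Kif20a by 2.52 ± 0.21 and Cenpa by 2.17 ± 0.18. Camera gave the mitosis genes an adjusted p of 7.97e-05, and an adjusted p = 0.699 with an estimated correlation. Oxidative phosphorylation genes rose in 60 of 71 cases and 11 did not pass (62 adjusted over the list alone), Atp5e by 2.19 ± 0.19 and Ndufb2 by 1.72 ± 0.17. Camera gave the oxidative phosphorylation genes an adjusted p of 1.4e-08, and an adjusted p = 0.699 with an estimated correlation. MYC target genes rose in 27 of 32 cases and 5 did not pass (28 rose and 1 fell adjusted over the list alone), with Hspe1 at 1.86 ± 0.17, Cad at 2.08 ± 0.25 and Myc at 2.65 ± 0.21. Camera gave the MYC target genes an adjusted p of 9.85e-06, and an adjusted p = 0.699 with an estimated correlation. With the actin difference of each array in the fit, their median went from 1.11 to 0.28 and the call was lost (0.0673). Ribosomal protein genes rose in 26 of 44 cases, fell in 1 and did not pass in 17 (29 and 1 adjusted over the list alone). Camera gave the ribosomal protein genes an adjusted p of 0.00395, and an adjusted p = 0.715 with an estimated correlation, and the call was lost with the stricter filter (0.0552) and with quantile normalization (0.148). In lists without a camera call, Pf4 (4.25 ± 0.48), Vwf (3.50 ± 0.59) and Gfi1b (2.91 ± 0.18) were higher and Cd14 (-2.81 ± 0.19) was lower. The stem cell factor receptor gene Kit (2.03 ± 0.50) and Gata2 (1.11 ± 0.27) passed, and did not without β-heterozygous replicate 1 (adjusted p = 0.0674 and 0.0576) or with α-null replicate 1 alone (0.0908 each). With the actin difference in the fit they stood at 1.33 ± 1.01 and 0.61 ± 0.52 (0.457 and 0.51), and Gata2 stood at 0.34 with quantile normalization (0.22). Eif2s3y (-3.47 ± 1.29, adjusted p = 0.0444) lost its call when any one array outside the β-floxed group and other than α-null replicate 1 was left out (0.0617 to 0.163), and stood at -5.26 without that replicate. It also lost the call with no filter (0.0535), median centring (0.0608), the trend and robust options (0.0547), only the groups compared (0.0816) and the actin difference in the fit (-2.51 ± 2.69, 0.608).

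The count fell to 374 with the actin 3′ minus 5′ difference of each array in the limma fit. This covariate separates the blocks, with 2.27 to 3.39 in the α-intact arrays and 1.21 to 1.69 in the α-null and double arrays. Quantile normalization moved the share of calls that were higher from 68.5% to 51.4%, and S100a9 and Lcn2 did not pass with α-null replicate 1 alone (-4.35 and -4.34, adjusted p = 0.0554 and 0.0511). With the covariate 10 reported genes lost the call. S100a9 stood at -4.75 ± 1.94 (0.193), Lcn2 at -5.11 ± 1.86 (0.157), Camp at -4.25 ± 1.37 (0.123) and Vwf at 3.10 ± 1.23 (0.183), so that the error grew more than the change shrank. Pf4 stood at 3.09 ± 0.88 (0.0985), Cad at 1.34 ± 0.42 (0.117) and Ndufb2 at 1.28 ± 0.28 (0.0549).

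Against the arrays labelled β-heterozygous (n = 2), the arrays labelled double (n = 3) addressed loss of both paralogs, again across the blocks. Mmp13 (log2 fold change 9.05 ± 0.18, SE), Mmp12 (8.86 ± 0.16), Bex1 (8.60 ± 0.86) and the fatty acid binding protein Fabp4 (8.03 ± 0.39) were higher. All 4 lay under 6.39 in the arrays labelled β-heterozygous, from 4.77 to 4.87, 5.53 to 5.69, 5.32 to 6.17 and 4.50 to 5.27, so the size of the change depends on how low the arrays can read. Granule genes were lower, Lcn2 by 178-fold (-7.47 ± 0.88) and Mpo by 169-fold (-7.40 ± 0.34). Of 14751 genes 7322 passed in limma, 4528 higher and 2794 lower, and 4070 changed at least 2-fold.

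Further increases came from Cd36 (7.95 ± 0.30), Atp6v0d2 (7.95 ± 0.16), the lysosomal protease Lgmn (7.82 ± 0.30), Clec4n (7.25 ± 0.26), Gpnmb (7.11 ± 0.27) and Procr (6.97 ± 0.58), and further decreases from Prtn3 (-7.05 ± 0.42), Camp (-6.92 ± 0.66), Cd177 (-6.77 ± 0.43), S100a9 (-6.74 ± 0.93), Ngp (-6.56 ± 0.88), Ltf (-6.34 ± 0.52), Ctsg (-6.33 ± 0.83) and Ifitm6 (-6.23 ± 0.29). All 35 mitosis genes fell (35 adjusted over the list alone), Cdc20 by -5.06 ± 0.23 and Mki67 by -3.93 ± 0.22, and 29 of 40 DNA replication genes fell with 11 not passing (32 adjusted over the list alone), Mcm7 by -3.72 ± 0.19. Camera gave the mitosis genes an adjusted p of 1.06e-20, and an adjusted p = 0.541 with an estimated correlation. Camera gave the DNA replication genes an adjusted p of 8.67e-13, and an adjusted p = 0.541 with an estimated correlation. Granulocyte genes fell in 16 of 22 cases, rose in 3 and did not pass in 3 (16 and 3 adjusted over the list alone). Camera gave the granulocyte genes an adjusted p of 1.3e-06, and an adjusted p = 0.541 with an estimated correlation. HOX/MEIS genes fell in 10 of 22 cases, rose in 2 and did not pass in 10 (10 and 2 adjusted over the list alone), with Myb at -4.65 ± 0.21, Hoxa9 at -3.74 ± 0.44 and the cytokine receptor Flt3 at -1.43 ± 0.26. Camera gave the HOX/MEIS genes an adjusted p of 0.0105, and an adjusted p = 0.541 with an estimated correlation. Cholesterol biosynthesis genes rose in 17 of 22 cases and 5 did not pass (18 adjusted over the list alone), Msmo1 by 3.13 ± 0.18, Mvd by 2.42 ± 0.23 and Sqle by 2.41 ± 0.24. Camera gave the cholesterol biosynthesis genes an adjusted p of 0.00049, and an adjusted p = 0.541 with an estimated correlation. Targets of p53 rose in 15 of 23 cases, fell in 1 and did not pass in 7 (16 and 1 adjusted over the list alone), Zmat3 by 3.83 ± 0.20 and Cdkn1a by 3.38 ± 0.39. Camera gave the p53 targets an adjusted p of 0.00426, and an adjusted p = 0.541 with an estimated correlation. Glycolysis genes rose in 13 of 19 cases, fell in 2 and did not pass in 4 (14 and 2 adjusted over the list alone), with Eno2 at 3.46 ± 0.26 and Hk2 at 1.94 ± 0.20. Camera gave the glycolysis genes an adjusted p of 0.0105, and an adjusted p = 0.541 with an estimated correlation. Camera passed 12 lists in all. Oxidative phosphorylation genes rose in 43 of 71 cases and fell in 1 (45 and 1 adjusted over the list alone), with quantile normalization ending that call (0.789), as the actin difference did (0.727). Camera gave the oxidative phosphorylation genes an adjusted p of 0.000131, and an adjusted p = 0.555 with an estimated correlation. Interferon-stimulated genes rose in 21 of 36 cases and fell in 3 (21 and 4 adjusted over the list alone), and ribosomal protein genes fell in 13 of 44 and rose in 4 (12 and 4 adjusted over the list alone). Camera gave the interferon-stimulated genes an adjusted p of 0.0122, and an adjusted p = 0.555 with an estimated correlation. Camera gave the ribosomal protein genes an adjusted p of 0.0105, and an adjusted p = 0.555 with an estimated correlation. Both calls were lost without β-heterozygous replicate 2 (0.108 and 0.0892), and the first also with the stricter filter (0.0928) and quantile normalization (0.0674). Cd68 (6.44 ± 0.32), Il7r (6.14 ± 0.41), Hmox1 (4.56 ± 0.36), Adgre1 (4.35 ± 0.20), Ifi204 (4.11 ± 0.31), Cdkn1c (3.94 ± 0.24), Bst2 (3.86 ± 0.31) and ferritin Fth1 (2.05 ± 0.19) were higher too. Without β-heterozygous replicate 1 and without replicate 2, Il7r stood at 5.50 and 6.77 and Ifi204 at 4.79 and 3.43.

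With the actin difference in the limma fit the count was 1652. Lcn2 (-7.28 ± 1.98, adjusted p = 0.0508), S100a9 (-6.03 ± 2.06, 0.102), Ngp (-6.26 ± 1.98, 0.0824), Flt3 (-1.30 ± 0.56, 0.174) and Cdkn1a (3.07 ± 0.85, 0.0538) then did not pass, with larger errors around changes of similar size. The glycolysis list did not pass either (0.34), and the stricter filter ended the glycolysis call too (0.0899). Quantile normalization moved the share of calls that were higher from 61.8% to 46.3%.

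The last comparison set arrays labelled double (n = 3) against arrays labelled β-floxed (n = 2), loss of α on a floxed β background, across the blocks. Mmp13 (log2 fold change 9.11 ± 0.18, SE) and Mmp12 (8.93 ± 0.16) were higher, under 6.39 in the arrays labelled β-floxed (4.64 to 4.87 and 5.41 to 5.67), so the size depends on how low the arrays can read. So were Atp6v0d2 (8.01 ± 0.16), the chemokine Ccl6 (7.75 ± 0.58), Gpnmb (7.64 ± 0.27), Clec4n (7.54 ± 0.26), Cd36 (7.32 ± 0.30), Lgmn (7.23 ± 0.30), the mannose receptor Mrc1 (7.17 ± 0.36) and lipoprotein lipase Lpl (6.89 ± 0.31). Mpo (-6.48 ± 0.34), Prtn3 (-6.00 ± 0.42), Fosb (-5.87 ± 0.25), Hoxa9 (-5.44 ± 0.44), Bcl11a (-5.36 ± 0.24), Nr4a2 (-5.34 ± 0.73), Myb (-5.29 ± 0.21), Cdc20 (-5.25 ± 0.23), Itih5 (-5.23 ± 0.77) and Egr1 (-5.03 ± 0.18) led the decreases. Without β-floxed replicate 1 and without replicate 2, Ccl6 stood at 6.47 and 9.03, Cd36 at 6.71 and 7.93, Mrc1 at 6.50 and 7.84, Mpo at -7.19 and -5.78, Prtn3 at -6.92 and -5.08, Hoxa9 at -4.62 and -6.25, Nr4a2 at -3.61 and -7.06 and Itih5 at -3.44 and -7.02. Of 14751 genes 5777 passed in limma, 2983 higher and 2794 lower, and 3579 changed at least 2-fold.

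Mitosis genes fell in 33 of 35 cases and 2 did not pass (34 adjusted over the list alone), Cdca8 by -3.78 ± 0.20, and DNA replication genes in 32 of 40 with 8 not passing (33 adjusted over the list alone), Mcm7 by -4.37 ± 0.19. Camera gave the mitosis genes an adjusted p of 1.61e-18, and an adjusted p = 0.316 with an estimated correlation. Camera gave the DNA replication genes an adjusted p of 1.87e-13, and an adjusted p = 0.316 with an estimated correlation. HOX/MEIS genes fell in 14 of 22 cases and 8 did not pass (14 adjusted over the list alone), with Erg at -3.59 ± 0.39 and Flt3 at -2.74 ± 0.26. Camera gave the HOX/MEIS genes an adjusted p of 4.32e-05, and an adjusted p = 0.316 with an estimated correlation. Stem cell markers fell in 13 of 27 cases, rose in 3 and did not pass in 11 (15 and 3 adjusted over the list alone), with the niche factor Angpt1 at -4.82 ± 0.54 (-3.64 without β-floxed replicate 1 and -6.00 without replicate 2), Sult1a1 at -3.13 ± 0.20, Gata2 at -1.99 ± 0.27 and Cdkn1c at 3.03 ± 0.24. Camera gave the stem cell markers an adjusted p of 0.0101, and an adjusted p = 0.632 with an estimated correlation. Cholesterol biosynthesis genes rose in 15 of 22 cases and 7 did not pass (16 adjusted over the list alone), Msmo1 by 4.12 ± 0.18 and Sqle by 2.04 ± 0.24. Camera gave the cholesterol biosynthesis genes an adjusted p of 4.32e-05, and an adjusted p = 0.316 with an estimated correlation. Monocyte, macrophage and dendritic cell genes rose in 13 of 24 cases, fell in 1 and did not pass in 10 (14 and 1 adjusted over the list alone), with Cd68 at 5.95 ± 0.32, Adgre1 at 4.64 ± 0.20 and Lyz2 at 3.97 ± 0.22. Camera gave the monocyte, macrophage and dendritic cell genes an adjusted p of 0.000528, and an adjusted p = 0.444 with an estimated correlation. Camera passed 15 lists in all, among them erythroid genes (13 of 22 fell, 1 rose, 14 and 1 adjusted over the list alone; adjusted p = 0.000712, and adjusted p = 0.316 with an estimated correlation), ribosomal protein genes (29 of 44 fell, 29 over the list alone; 3.05e-07, and adjusted p = 0.329 with an estimated correlation) and immediate early and heat shock genes (18 of 31 fell, 3 rose, 19 and 4 adjusted over the list alone; 0.000528, and adjusted p = 0.396 with an estimated correlation). Itgam (4.74 ± 0.21), Ifi204 (5.00 ± 0.31), Zmat3 (2.60 ± 0.20) and Tigar (2.42 ± 0.24) were higher as well.

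The stem cell marker and the macrophage calls were lost without β-floxed replicate 1 (median from -1.40 to -0.35, adjusted p = 0.183, and from 1.39 to 0.73, 0.109), the array that stood apart on the third component. Without replicate 2 these medians were -2.42 and 2.54, and the stem cell call was lost with the actin difference (0.127). The count was 3810 with array weights and 1600 with the actin difference in the limma fit, where Nr4a2 (-5.29 ± 1.92, adjusted p = 0.12), Itih5 (-6.17 ± 2.00, 0.0885), Angpt1 (-3.90 ± 1.38, 0.113), Sqle (1.37 ± 0.53, 0.143) and Tigar (2.02 ± 0.59, 0.0641) did not pass, each with an error more than 2-fold larger.

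**Figure D4:**
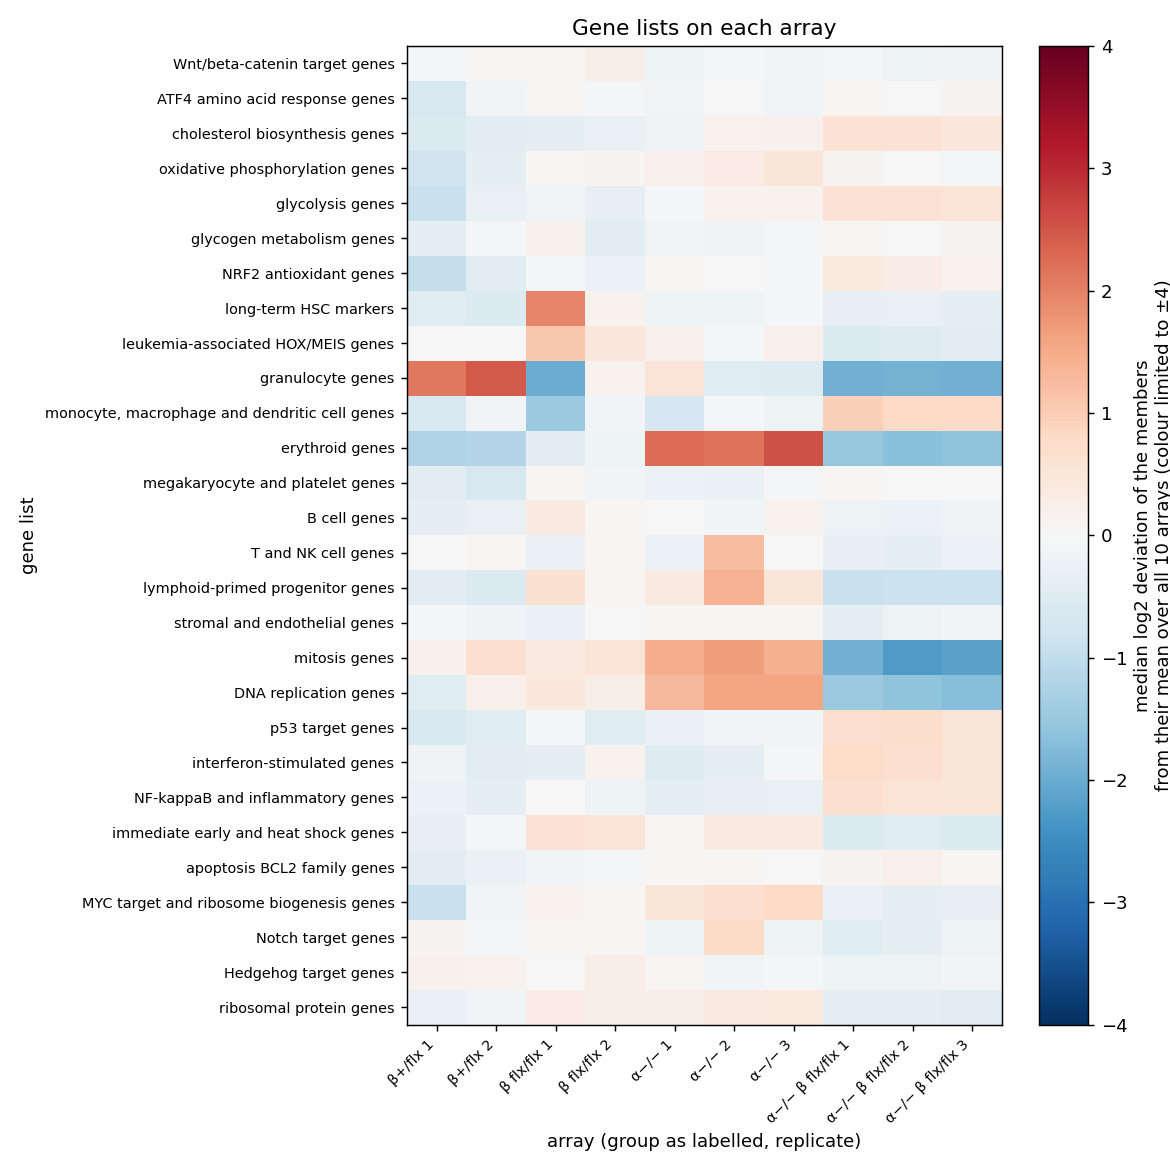
Median log2 deviation of each gene list's members from their mean over the 10 arrays (colour, limited at 4 above and below), with lists as rows and arrays as columns. Granulocyte genes are high in the arrays labelled β-heterozygous, erythroid genes in those labelled α-null, and mitosis genes low in the 3 arrays labelled double.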

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

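The tests of macrophages, neutrophils, a lower share of sorted cells, the α-null arrays at odds with their sex label, the blocks and erythroid cells, and the count of lists over other splits of the arrays, were chosen after the results were seen.

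The difference between arrays labelled with both β alleles floxed and their baseline depended on the α label for 5464 genes, by limma's test of the interaction. The 2 baselines differ in the number of β alleles kept, and Gsk3b itself did not pass with all arrays. The β-heterozygous arrays, with their high granulocyte genes, enter this interaction too. Whether it came from the alleles was not tested. The largest positive differences were those of Mmp8 (9.75), Mmp12 (9.35), Mmp13 (8.98), Chil3 (8.90) and Cybb (8.73) on the log2 scale. The largest negative ones were those of Hemgn (-9.15), Aldh1a1 (-8.96), Dntt (-8.43), Car2 (-7.76) and Aqp1 (-7.68). Median differences above 0 were found for granulocyte (3.19), monocyte, macrophage and dendritic cell (1.35), interferon-stimulated (0.70), inflammatory (0.54) and cholesterol biosynthesis genes (0.51). The granulocyte median itself was below 0 with α intact (-2.43) and with α absent by label (-1.435). Medians below 0 were found for erythroid (-4.96), mitosis (-3.74), DNA replication (-3.51), lymphoid-primed progenitor (-2.56), stem cell marker (-1.81), MYC target (-1.47), ribosomal protein (-1.30), HOX/MEIS (-1.29), immediate early and heat shock (-1.21) and oxidative phosphorylation genes (-0.93). With an estimated correlation these lists did not pass, at adjusted p from 0.0945 for erythroid genes to 0.734 for stem cell markers, and their counts stand with the comparison. The poly-A spikes, control probe sets outside the tested genes, were higher by 2.30 log2 units in the arrays labelled β-floxed than in those labelled β-heterozygous. These groups thus differed in a technical measure too, and its part in their comparison was not tested.

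In the arrays labelled double, macrophage genes were higher and cell cycle genes lower than in those labelled α-null. Macrophages that gave a minority of the RNA, beside otherwise unchanged sorted cells, would leave mitosis genes at or above -1 log2 unit. The upper quartile of their changes, -2.86, argues against this. The bound concerns shares of RNA, so a minority of macrophages by cell number could not be judged. With macrophages in place of most of the sorted cells the list would rise, and of 24 members 18 had higher values, 10 of them past the threshold (11 adjusted over the list alone, 2 past it as lower), but this restates the pattern and decides nothing, nor did a count by rank among other probe sets, which was tried first. A lineage-negative gate would remove macrophages, 1 member belongs to another list, and a change in the sorted cells through loss of both paralogs was not tested, so both stay open. Of the 10 splits of the 6 arrays, too few for a share under 0.05, 1 gave as many genes (the real one with 5561, highest other 0) and 7 as many lists by camera (real 14, highest other 16), so the number of lists does not set the real split apart.

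Granulocyte genes were higher in the arrays labelled β-heterozygous than in those labelled β-floxed. A lower share of the sorted cells that raised the markers of all other cell types alike would raise erythroid genes there too. The lower quartile of the erythroid changes, 0.14, lay above the upper quartile of the granulocyte changes, -1.58. This argues only against such a like rise. A lower share with neutrophils in place of sorted cells was not tested by it. Of 27 stem cell markers, 12 were higher in the β-floxed arrays and 0 lower. With neutrophils among the sorted cells of the β-heterozygous arrays the list would be lower in the β-floxed ones, and all 22 members had lower values, 16 of them past the threshold (19 adjusted over the list alone), but this restates the pattern and decides nothing, nor did a count by rank among other probe sets, which was tried first. The lineage-negative gate would remove neutrophils, 1 list member belongs to another list, and this stays open. An effect of the second floxed allele was not tested apart from such neutrophils and stays open.

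Erythroid genes were higher in the arrays labelled α-null than in the other groups. With α-null replicate 1 alone, whose sex-linked genes fitted its label, their median against β-heterozygous was 3.66, which argues against the other α-null arrays as the whole cause. A difference between the blocks that acts alike on both groups would raise them in the arrays labelled double too. There the upper quartile, 0.12, lay below the lower quartile in the arrays labelled α-null, 2.33. This argues only against such a like shift. A block difference hidden by other changes in the double arrays could not be excluded. Erythroid cells could not be judged. A lineage-negative gate would remove those that carry lineage markers, but not earlier ones, which were not tested apart. Of 3 adult globin genes with a probe set of their own, 1 was higher. Hbb-b2 went from 4.88 to 9.46, while Hba-a1 (6.54 and 6.38) and Hba-a2 (8.38 and 7.63) were not higher. Group means of Hba-a1 lay from 6.38 to 6.67, near the filter level of 6.39, so it could tell little. The set was widened to all 3 after Hbb-b2 alone had been tried with the values known. Loss of α, with both β alleles kept, was not tested apart from these and stays open.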

How the results depend on the processing

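Using α-null replicate 1 alone and the actin difference as a covariate were chosen after the data were seen. The cause of the changes was not tested. Fewer arrays did not always lower the count. With only the groups compared, 7813 genes passed for double against α-null and 5208 for double against β-floxed. Against β-heterozygous, 7855 passed for α-null, 8610 for double and 59 for β-floxed. The main fit shares 1 spread over all groups. The median SD of a gene was 0.23 in β-heterozygous and 0.29 in β-floxed arrays, against 0.16 in α-null and 0.11 in double arrays. Of 269 pairs of gene and comparison reported, 2647 outcomes with an array left out kept direction and side of the threshold, 32 lost the call, 3 gained it and 8 reversed. Under other settings these numbers were 2823, 91, 2 and 11. Over all 753 pairs the rule names they were 7286, 178, 55 and 11 with an array left out and 7608, 450, 47 and 31 otherwise, so calls outside the reported part were lost more often. Of the lost calls with an array left out, 95 concerned β-floxed against β-heterozygous. Of 74 list calls, 701 outcomes with an array left out were kept, 38 lost and 1 reversed, and under other settings 749 were kept and 124 lost, 74 of them with an estimated correlation. The stricter filter ended 11 list calls, 8 of them given with their comparison and the others NRF2 for double against β-heterozygous (0.165) and glycolysis (0.119) and inflammatory genes (0.0911) for double against β-floxed. When an array left out leaves 1 in its group, that array is assumed to vary like the other groups.

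Genes passing for β-floxed against β-heterozygous (2701) numbered 270 with array weights, 59 with only the groups compared, 1623 with α-null replicate 1 alone, 1678 at 2-fold, 4192 at an unadjusted p and 1.5-fold, and 968 to 6011 with an array left out. For double against α-null (5561) they numbered 8464 with weights, 2885 with replicate 1 alone and 3438 at 2-fold. For α-null against β-heterozygous (7665) they numbered 2328 with replicate 1 alone, 374 with the actin covariate and 4136 at 2-fold. Double against β-heterozygous (7322) gave 1652 with the covariate and 4070 at 2-fold, double against β-floxed (5777) gave 3810 with weights, 1600 with the covariate and 3579 at 2-fold, and the interaction (5464) gave 3331 with replicate 1 alone. Median shifts of all genes moved with quantile normalization from 0.15 to 0.03, from 0.20 to -0.01 and from 0.05 to -0.08 in the comparisons with β-heterozygous arrays. Lists passing for β-floxed against β-heterozygous numbered 6 with quantile normalization against 11, and 0 in every comparison with an estimated correlation.

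Replicate numbers did not pair the samples: 13 same-numbered pairs correlated at -0.336 to 0.297, 2 above 0.1. With the replicate block, 1672 genes passed for β-floxed against β-heterozygous. Of the reported genes, 1 lost its call in that comparison (Ccnd1) and 1 for α-null against β-heterozygous. Gsk3a stood at 0.011 for α-null against β-heterozygous.

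Gsk3a, without a call there, also turned to 0.073 with median centring and ranged from -0.28 to 0.14 with an array left out, and for β-floxed against β-heterozygous it turned to -0.007 with quantile normalization. Gsk3b, without a call in any comparison with all arrays, passed without β-floxed replicate 2 for β-floxed against β-heterozygous (0.00473), double against β-floxed (0.0144) and the interaction (0.0216), without replicate 1 for double against β-floxed (0.0406), and by the mean of its probe sets for double against β-heterozygous (0.50, 0.0342). It changed sign with quantile normalization for α-null (-0.59) and double (-0.32) against β-heterozygous and the interaction (0.22), with the mean of its probe sets for double against β-floxed (0.41) and the interaction (0.22), and with the covariate for the same comparisons (1.15 and 0.08). With an array left out it ranged from -0.43 to 1.32 for β-floxed against β-heterozygous, -0.29 to 0.54 for α-null and -0.082 to 0.75 for double against β-heterozygous, -0.99 to 0.76 for double against β-floxed, and -1.11 to 0.64 for the interaction. Eif2s3y for α-null against β-heterozygous turned from -3.47 to 0.10 with α-null replicate 1 alone. The macrophage list for β-floxed against β-heterozygous ranged from -0.68 to 0.53.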
